A study of Homo sapiens with 63 samples.

How the data were processed

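CD45+ cells from autopsy tissue or surgical resections were profiled in 63 droplet libraries of 10x Genomics 3′ chemistry, per the labels. The chemistry version of each library is not given in the sources used here. The authors deposited gene counts (UMIs per gene and barcode), which were made with Cell Ranger 3.1.0 on hg38, per the submitters' processing notes. Counts of hashtag and surface antibodies lie in the same deposited matrices of the hashed libraries, which hold 27 antibody features, 17 of them surface antibodies. The matrices hold 27984 genes. Positions were taken from GENCODE 29 (GRCh38, 1-based) for the 27806 genes found there, and 6 gene names of the lists were matched through their Ensembl identifiers. Of all genes, 758 were kept out of tests (Y-linked and X-inactivation genes, mitochondrial genes, immunoglobulin and T cell receptor segments, genes of variable copy number).

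Barcodes were kept with at least 500 UMIs, 300 genes and at most 20% mitochondrial UMIs. Hashtag doublets were removed, and each hashed library was used whole as its donor. Doublets were also scored with a re-implementation of the Scrublet procedure at 0.8% per 1000 barcodes. Its automatic threshold marked 177 cells, too few for a working threshold, so it was not used, and an alternative left out the top-scoring 5834 cells. Cells were clustered into 50 clusters on 30 principal components of 2000 variable genes (k-means, seed 1). Clusters were named with 14 marker sets. The microglial class needed at least 8 of 12 microglial markers and no more leading genes of another cell type than of its own, and the second rule, set after the leading genes were seen, kept cluster 7 out. Macrophages at the borders of the brain share markers with microglia and were not separated, hence the class name microglia and macrophage-like.

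Total UMIs per library were 3713064 to 45493833 in ALS (18 libraries, 49030 cells), 1634040 to 21115561 in LOAD (23, 53516), 65525 to 10537558 in DLBD-PD (7, 15118), 3473143 to 11055857 in EOAD (2, 3604), 8097539 to 36702113 in MS (4, 14616) and 1586425 to 3352800 in PSP (3, 5913). FTD (2, 3137), ALS/FTD (1, 7602), CNTRL (1, 7119) and the pools without a group (2, 8896) are described only. A donor or library with fewer than 50 microglial cells was left out of a test, and shares needed at least 200 cells and a mean share of at least 0.1%, which 6 classes reached. At 0 counted T or NK-like cells, a donor with 1402 cells leaves an upper 95% bound of 0.263%.

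Counts of the microglial class were summed per donor and tested in 1 edgeR quasi-likelihood fit over all diseases, with library format (hashed or single-region) as covariate, TMM scaling and filterByExpr (14252 genes). Each disease was compared with LOAD, so all disease comparisons share the LOAD donors. Regions were compared in single-region libraries with matching labels (BA9 6, BA4 3, H 3, SC 3, SN 2, FN 2 libraries), with donor as block (12789 genes). The donors with both regions were ALS 1, ALS 4 and ALS 5 for SC against BA4, ALS 1 and ALS 4 for FN against BA4 and for BA4 against BA9, FTD 1, LOAD 12 and LOAD 15 for H against BA9, and DLBD-PD 3 and LOAD 15 for SN against BA9. The pairing comes from the donor names in the labels. Checked on 8397 genes, deviations from the region means had a median correlation of 0.424 in 20 pairs of libraries of the same donor (18 over 0.1) and −0.029 in 156 pairs of different donors. Libraries of a donor also share disease and barcode set, so these correlations cannot show by themselves that the donor names are right. No library was a duplicate of another (1953 pairs, lowest chi-square per degree of freedom 1.688). A Benjamini-Hochberg adjusted p under 0.05 was required throughout. Standard errors of log2 fold changes come from the fit, and CPM are given as mean ± SD over donors or libraries.

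The 24 gene lists were fixed before the data were examined: homeostatic, lipid-associated, interferon, MHC class I and II, chemokine and NF-kB, immediate early, heat-shock, hypoxia, oxidative-phosphorylation, iron, complement, phagocytic, cholesterol, proliferation and lysosome genes, and markers of border macrophages, monocytes, T cells, astrocytes, oligodendrocytes, neurons, vascular cells and erythroid cells. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (limma), and members were also adjusted over the list alone. Shares of classes were compared by exact permutation of donors within library format, and within donors by sign flips.

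Genes were named by a rule fixed in advance: up to 10 genes per direction with the largest fold changes (5 where a group has 2 donors) among genes that passed, reached 10 CPM in a group and had the same sign in each format or donor, and the leading 4 members of each called list. Y-linked, X-inactivation, mitochondrial, immunoglobulin and T cell receptor genes are never named, nor are genes of variable copy number. Some genes that the rule names are not reported here. Near-identical copies (HSPA1A and HSPA1B, HBA1 and HBA2, the FCGR family, HLA genes) share reads, so their values are uncertain.

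The disease test was run on simulated data with known changes. The simulated counts, here and for the region test, held no difference between barcode sets, formats or donors, so the rates do not cover such differences. Of genes changed by a log2 fold of 1, and of 2, it recovered 49% and 86.7% in ALS (14005 genes), 31.3% and 74.7% in DLBD-PD (14024), 10.2% and 66.3% in EOAD (14018), 13.4% and 66.7% in MS (14036) and 10.1% and 50.5% in PSP (13938), with 5 false among 138 calls in ALS. The region test recovered 64.1% and 89.8% in SC (12025 genes), 50% and 80.6% in FN (12053), 46.9% and 78.9% in H (11947), 41.1% and 74% in SN (12022) and 47.4% and 84.4% in BA4 against BA9 (12018), with 10 false among 157 calls in SC.

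Alternatives were DESeq2, RLE scaling, no low-count filter, stricter cells (1000 UMIs, 500 genes, 10% mitochondrial), top-scoring doublets left out, cells with P2RY12, CX3CR1 or CSF1R only, a minimum of 20 cells, no format covariate or no block, 1 format or barcode set only, 3 library batches (format by barcode set), clusters led by macrophage or stress genes left out, cluster 7 counted, conflicting labels left out or read by title or tissue tag, and leaving out each donor. A cluster counted as macrophage-led where its leading genes held more macrophage than microglial markers, so such markers need not be at its top. Barcode set A or B was read from the barcodes of each library. In all, 15 libraries of 6 donors carry 2 different region labels and entered disease tests but not region tests. Cells of hashed libraries were not assigned to regions, because the labels do not tie tags to regions. Genes with 0 counts in a group are given as values without a fold.

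Tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, statsmodels 0.14.6 and matplotlib 3.10.9.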

Results

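The series asks how CD45+ cells of the human brain, most of them microglia, differ between diseases and between regions. It holds 63 droplet libraries from donors with LOAD, ALS, DLBD-PD, EOAD, MS, PSP, FTD or ALS/FTD, from 1 CNTRL donor and from 2 pools of 2 donors each. Disease and region codes (LOAD, ALS, SC, FN, H, SN and the BA areas) are used as the labels give them. Of the libraries, 41 came from 1 region each and 22 were hashed, which means that several regions of a donor were tagged and pooled. Donors are the replicates: 16 LOAD, 8 ALS, 4 DLBD-PD, 2 EOAD, 2 MS and 2 PSP. The hashed ALS pools combined BA9, BA4 and SC, and most hashed LOAD pools combined BA9, BA20 and H, so disease and region are mixed in them. The MS libraries were labelled BA9, TH, AWS and, in MS 2, lesion, those of DLBD-PD BA9 and SN, and those of PSP BA9, H and SN. The mix of regions in MS, DLBD-PD and PSP thus differs from that in LOAD as well, although some LOAD libraries were also labelled BA9, H or SN. The 2 EOAD libraries were hashed pools of BA9, BA20 and H, the regions of most hashed LOAD pools. Of 235484 barcodes in the deposited count matrices, 177698 passed the quality filters, and 168551 remained after 9147 hashtag doublets were removed. Libraries held 36 to 7854 such cells, with a median of 682 to 7182.5 UMIs per cell.

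Microglia made up most of the CD45+ cells. The class called microglia and macrophage-like held 150229 cells and was led by SPP1, APOE, C1QC, C1QA, TREM2 and CD74, genes of lipid handling, complement, phagocytic signalling and antigen presentation. T and NK-like cells (4133) expressed CCL5, NKG7, IL7R and CD2, genes of cytotoxic and T lymphocytes. Monocyte-like cells (570) expressed VCAN, S100A12 and FCN1. Small classes carried markers of neurons (1275 cells), astrocytes (339), erythroid cells (262) and oligodendrocytes (220), and 11523 cells stayed without a name. Most unnamed cells (8561) formed cluster 7, where S100A9, S100A8, HAMP and CD14 were highest. Cluster 7 also expressed microglial markers but was led by markers of another cell type, so it was kept out of the microglial class. Its mean share per donor, not tested, was 10.04% in ALS (0.01 to 42.71), 2.9% in LOAD (0 to 21.04), 3.34% in MS, 0.13% in DLBD-PD, 0% in EOAD and 0.05% in PSP.

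T and NK-like cells took a larger share of the CD45+ cells in ALS than in LOAD. They made up 5.106 ± 3.527% (mean ± SD, n = 8 donors) in ALS and 1.781 ± 2.172% (n = 16) in LOAD, a difference of 3.325 points (exact permutation within library format, BH-adjusted p = 0.0109 over 6 classes). In 3 hashed LOAD donors no T or NK-like cell was found among 3193, 4338 and 1402 cells, which leaves upper 95% bounds of 0.115%, 0.085% and 0.263%. Monocyte-like cells were also more frequent in ALS (0.366 ± 0.212% against 0.108 ± 0.104%, adjusted p = 0.0022, exact permutation), as were neuron-like cells (1.851 ± 2.708% against 0.14 ± 0.291%, adjusted p = 0.0176, exact permutation). The microglial class was smaller in ALS (79.66 ± 12.815% against 93.295 ± 5.172%, adjusted p = 0.0027, exact permutation). With cluster 7 counted in it the difference was −6.493 points instead of −13.635 (adjusted p = 0.0154, exact permutation). The call held in single-region donors (−13.804 points, adjusted p = 0.0143, exact permutation) and in those with matching region labels (−18.148 points, adjusted p = 0.0179). In other subsets the call was lost although the difference was no smaller: −13.906 points in hashed donors (adjusted p = 0.0749, exact permutation), −19.739 outside SC (adjusted p = 0.0714) and −21.937 in BA9 alone (adjusted p = 0.1429). Without SC but with ALS 3, it held by title (−15.499 points, adjusted p = 0.0476, exact permutation) and not by tissue tag (−14.111 points, adjusted p = 0.0857). Astrocyte-like (0.09 points, adjusted p = 0.6195) and erythroid-like shares (0.46 points, adjusted p = 0.1007) did not pass the exact permutation test over all donors. In single-region donors both passed (0.609 and 0.921 points, adjusted p = 0.0095 each, exact permutation), and the astrocyte-like share also passed outside SC (0.746 points, adjusted p = 0.0357), but in hashed donors they stood at −0.345 and 0.003 points. The erythroid-like difference rests on ALS 1 and was 0.008 points without that donor. The T and NK difference was 2.797 points in single-region donors (exact permutation p = 0.0143) and 3.991 points in hashed donors (adjusted p = 0.1139). The test does not take the barcode set into account, and within set B the difference was 3.121 points and did not pass (adjusted p = 0.0679, exact permutation). In single-region donors with matching region labels it was 2.789 points (n = 3 and 6, exact permutation p = 0.03571), without their SC libraries −0.533 points (p = 0.46429) and in BA9 alone −0.571 points (n = 2 and 6, p = 0.5), so in these donors the higher share rests on SC libraries. ALS 3, whose region labels conflict, is not among them, and with ALS 3 the difference without SC was 0.701 points by title (exact permutation p = 0.78571) and −0.727 by tissue tag (p = 0.11429). The monocyte-like call was lost with the stricter quality filter (0.128 points, adjusted p = 0.0779, exact permutation), in hashed donors (0.247 points, adjusted p = 0.0749), outside SC (0.193 points, adjusted p = 0.3571) and in BA9 alone (0.057 points, adjusted p = 0.6429). The neuron-like difference was 0.878 points instead of 1.71 without ALS 1, which held 7.677% (adjusted p = 0.0441, exact permutation). It was −0.116 points in hashed donors, and its call was lost in barcode set B (1.646 points, adjusted p = 0.5594, exact permutation) and in BA9 alone (9.289 points, adjusted p = 0.1071).

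**Figure D1:**
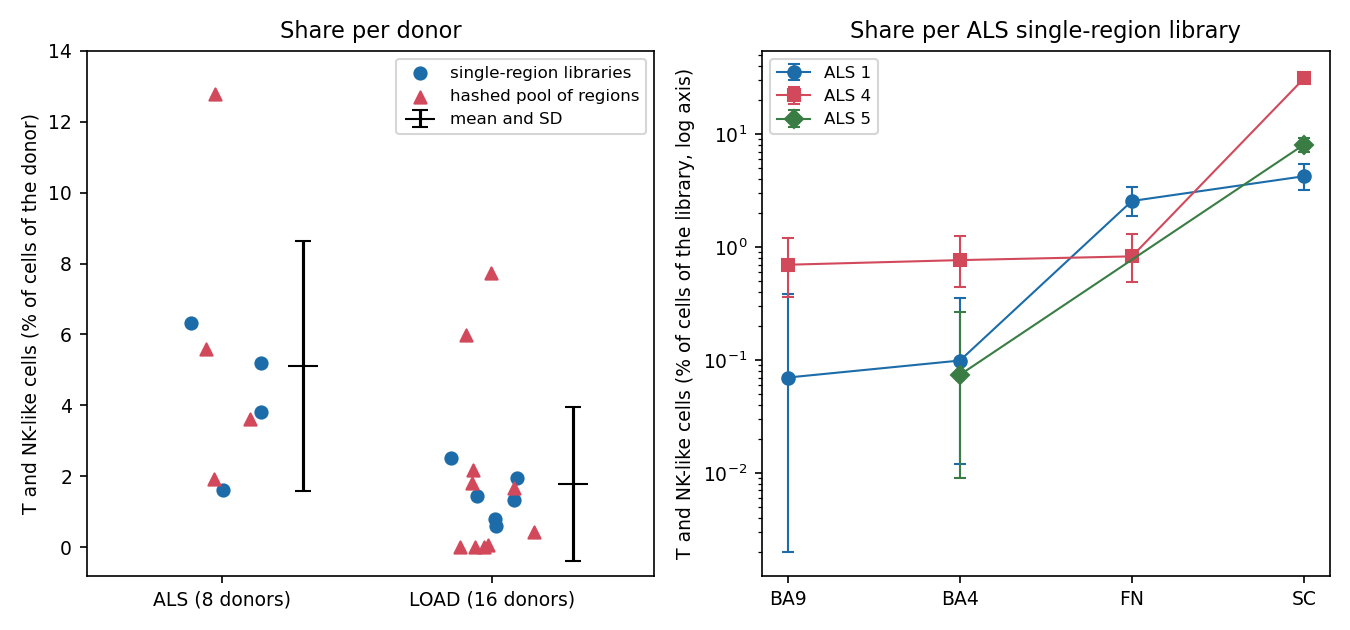
Share of T and NK-like cells per donor in ALS and LOAD, by library format, and per single-region library of 3 ALS donors with 95% intervals.

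Within donors, SC held far more T and NK-like cells than BA4. In ALS 4 they were 31.231% of SC cells (95% interval 28.749 to 33.797) and 0.768% of BA4 cells, in ALS 5 8.105% (7.029 to 9.287) and 0.074%, and in ALS 1 4.251% (3.235 to 5.472) and 0.099%. The mean difference was 14.215 points (SD 14.204, n = 3 donors, exact sign-flip permutation p = 0.25). That p is the smallest that 3 donors can give, so the test cannot fall below 0.05. FN libraries held 2.566% in ALS 1 and 0.83% in ALS 4. The libraries of ALS 3 carry conflicting region labels and were not part of the comparison. By tissue tag its SC library held 11.97% and its BA4 library 0.084%. By title the order was reversed, with 0.109% in its SC library and 11.97% and 4.028% in its libraries titled GM.

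In the microglial class, ALS donors showed higher expression of NRARP and of genes of cholesterol synthesis than LOAD donors, whose libraries hold no SC or FN. NRARP, which encodes a feedback regulator of Notch signalling (ENSG00000198435, chromosome 9, 137300482 to 137302251, minus strand), had a log2 fold change of 3.82 ± 0.59 (SE) and 39.9 ± 63.1 against 3.67 ± 4.87 CPM (mean ± SD, n = 8 and 16, edgeR adjusted p = 0.00376). SUCNR1, the succinate receptor (chromosome 3, 151873643 to 151884619, plus strand), rose 2.36 ± 0.47, from 4.67 ± 4.37 to 24.1 ± 13.9 CPM (edgeR adjusted p = 0.0285). MSMO1, a sterol oxidase of cholesterol synthesis (chromosome 4, 165327623 to 165343160, plus strand), rose 1.68 ± 0.33, from 18.2 ± 11.3 to 62.6 ± 51.3 CPM (edgeR adjusted p = 0.0269). ALYREF, an mRNA export factor (chromosome 17, 81887844 to 81891586, minus strand), rose 1.18 ± 0.19 (edgeR adjusted p = 0.00419). CMYA5 (2.43 ± 0.49), the bromodomain gene CECR2 (1.99 ± 0.42) and UBE2M, which encodes a NEDD8-conjugating enzyme (0.81 ± 0.17), were higher too. SERPINF2, the gene of alpha-2-antiplasmin, fell by 1.21 ± 0.26, from 14.5 ± 7.07 to 6.19 ± 1.55 CPM (edgeR adjusted p = 0.0363). NRARP, SUCNR1, MSMO1 and ALYREF lay above the LOAD median in 8 of 8 ALS donors. In single-region ALS libraries NRARP stood at 2.97 to 7.04 log2 CPM in FN and SC but at −0.17 to 0.65 in BA9 and BA4, beside −0.96 and 0.13 in BA9 of LOAD 12 and LOAD 15, so its rise lies in FN and SC. SUCNR1 stood at 4.16 to 6.22 log2 CPM in BA9 and BA4 of ALS and at 1.76 and 0.74 in BA9 of LOAD 12 and LOAD 15. These ALS libraries belong to barcode set B and those of LOAD 12 and LOAD 15 to set A, so disease and barcode set cannot be told apart here. In BA9 of DLBD-PD 3, of set B, SUCNR1 stood at 2.86. MSMO1 stood at 4.08 to 5.04 log2 CPM in BA9 and BA4 of ALS, beside 4.93 and 3.79 in BA9 of LOAD 12 and LOAD 15. In FN and SC of ALS it stood at 5.02 to 8.44, so its highest values lie in FN and SC. NRARP is also among the leading genes of clusters 22 and 25 of the class, which are led by stress-response genes. Cluster 4 had the highest mean share of the class per donor in ALS (12.28%, 0.57 to 27.31) and cluster 10 in LOAD (10.26%, 0.09 to 72.93). Cells of cluster 4 held few UMIs (median 0.426 of the library median) and a median of 10.3% mitochondrial UMIs.

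Of 14 genes of cholesterol synthesis and efflux, 2 rose over all genes and 10 rose when adjusted over the list alone (median 0.65, camera adjusted p = 5.16e-10 with the preset correlation, and adjusted p = 0.00314 with an estimated correlation). SQLE, the squalene epoxidase gene of the same pathway as MSMO1, stood at 1.06 ± 0.37 (edgeR adjusted p = 0.213). The cholesterol exporter gene ABCA1 stood at −0.21 ± 0.39, and INSIG1, another member, is a leading gene of the stress-led clusters 22 and 25. The median was 0.629 in hashed donors (adjusted p = 0.341 with an estimated correlation) and 0.981 in single-region donors (adjusted p = 0.188 with an estimated correlation). Immediate early genes were called upward (12 of 14 above 0, 2 rose over the list alone, camera adjusted p = 0.00139), but not with an estimated correlation (adjusted p = 0.846) nor in single-region donors (camera adjusted p = 0.234). FOS stood at 0.33 and ATF3 at 1.30. Heat-shock genes (camera adjusted p = 0.112), T cell markers (median 1.302, p = 0.112), proliferation genes (median 1.474, p = 0.26), MHC class II (p = 0.665), homeostatic (p = 0.641) and lipid-associated genes (p = 0.628) were not called.

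In all, 26 of 14252 genes passed in ALS against LOAD (24 up, 2 down, edgeR), against 193 by DESeq2 (99 up, 94 down). The result depends on library format: edgeR called 379 genes in single-region donors, with all 11 named genes among them. It called 0 in hashed donors, where 1822 genes lay under an unadjusted p of 0.05. The 11 named genes kept their direction there, but the naming rule asks for the same sign in each format, so this adds no support. In single-region libraries ALS and LOAD also differ in barcode set, since all ALS donors belong to set B and 5 of 6 such LOAD donors to set A. Fitting format and barcode set as 3 library batches gave 1015 genes, and 438 after LOAD 26, the only single-region LOAD donor of set B, was also left out. Set B alone gave 511, with 4 of the named genes among them. In BA9 libraries alone 2 of 10 named genes kept their call, and MSMO1 stood at −0.02. Leaving out 1 donor gave 6 to 73 genes.

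**Figure D2:**
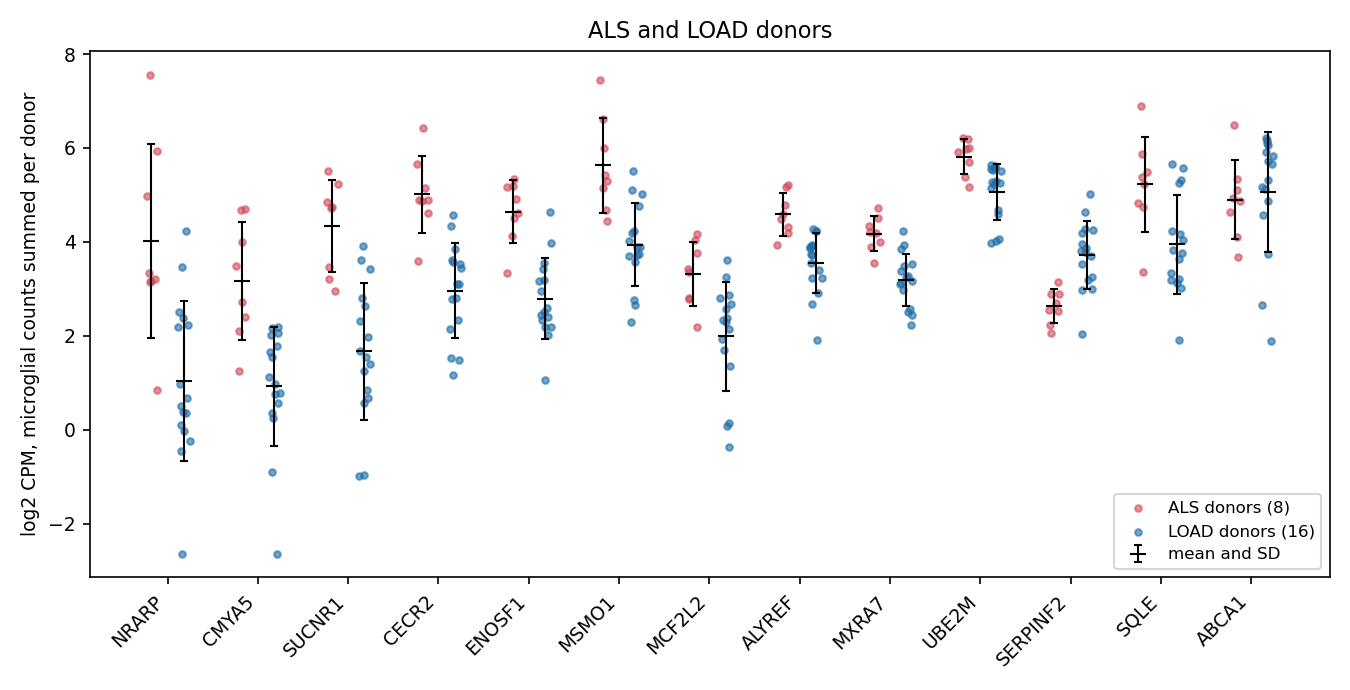
Expression of named genes in the microglial class of each ALS and LOAD donor, in log2 CPM with mean and SD.

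Monocyte and iron-handling genes were called lower in microglia of DLBD-PD than of LOAD donors, as lists and not as single genes. Of the 6 monocyte markers, all lay below 0 and 5 fell when adjusted over the list alone (camera adjusted p = 4.19e-05, adjusted p = 0.0235 with an estimated correlation). S100A8, a calcium-binding alarmin (chromosome 1, 153390032 to 153391188, minus strand), stood at −3.37 ± 1.35, with 28.4 ± 26.8 against 209 ± 299 CPM (n = 4 and 16), its partner S100A9 at −3.00 ± 1.19 and the proteoglycan gene VCAN at −3.45 ± 0.95. S100A9 is also a leading gene of cluster 10 of the class, beside the macrophage marker F13A1. That cluster had the highest mean share per donor in LOAD (10.26%, 0.09 to 72.93). Of 12 iron genes, 11 lay below 0 and 4 fell over the list alone (median −0.592, camera adjusted p = 0.00177, adjusted p = 0.0235 with an estimated correlation). The ferritin gene FTH1 stood at −0.89 ± 0.52 and the iron exporter gene SLC40A1 at 0.41. The iron list depends on library format: it was not called in hashed donors (camera adjusted p = 0.183), where the ferritin light chain gene FTL stood at 0.52 and HMOX1, which degrades heme, at 1.11, against −0.89 and −1.1 in single-region donors. Of 11 phagocytic genes, 10 lay below 0 (median −0.755, camera adjusted p = 0.000596, but adjusted p = 0.0668 with an estimated correlation), with the scavenger receptor MSR1 at −0.96 ± 0.30. Hypoxia genes (16 of 16 below 0, median −0.97, camera adjusted p = 4.19e-05, VEGFA −1.75 ± 0.77) and lipid-associated genes (19 of 20, median −0.857, adjusted p = 0.000228, SPP1 −1.38 ± 0.52) were called downward. So were complement (9 of 11, camera adjusted p = 0.00354), MHC class I (9 of 12, p = 0.00354), oxidative phosphorylation (30 of 30, p = 0.00354), cholesterol (12 of 14, p = 0.00203), lysosome (12 of 15, p = 0.0319), astrocyte (7 of 8, p = 0.0383), neuron (6 of 7, p = 0.0291) and erythroid genes (3 of 3, p = 0.00397). With the phagocytic list, these 11 lists lost the call, with adjusted p = 0.0668 to 0.726 with an estimated correlation. HBB, a hemoglobin gene, had 0 CPM in DLBD-PD and 2.44 ± 2.44 in LOAD. Cluster 3 had a mean share of 23.26% per DLBD-PD donor (0.03 to 48.18). Cluster 20, led by stress genes, averaged 20.88%, because it held 83.51% of the class in DLBD-PD 4, the hashed donor, whose library gave 93.6% of its cells.

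No gene passed in DLBD-PD against LOAD by edgeR, where 1613 lay under an unadjusted p of 0.05, and DESeq2 called 93 (22 up, 71 down). Hashed donors alone, with 1 DLBD-PD donor, gave 53. In barcode set A the direction of the MHC class I list was reversed (camera adjusted p = 0.973).

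In EOAD microglia, from 2 donors, APBB3 and LRRC57 were above every LOAD donor in both. APBB3, the gene of an adaptor that binds the amyloid precursor protein (chromosome 5, 140558268 to 140564781, minus strand), rose 1.82 ± 0.33, from 18.3 ± 3.60 to 66.3 ± 35.2 CPM (n = 2 and 16, edgeR adjusted p = 0.0178). LRRC57 (1.51 ± 0.26, edgeR adjusted p = 0.0147) and HAUS2, which encodes a spindle protein (1.24 ± 0.24, adjusted p = 0.0379), are divergent neighbours on chromosome 15 (42537820 to 42548802, minus strand, and 42548810 to 42569994, plus strand), and HAUS2 stood at 4.22 log2 CPM in EOAD 1, within the LOAD range (3.48 to 4.43). RANBP3L, which encodes a Ran-binding protein (chromosome 5, 36248434 to 36302114, minus strand), rose 5.16 ± 0.81, from 0.382 ± 0.547 to 15.5 ± 21.3 CPM (edgeR adjusted p = 0.00594), which rests on EOAD 1 (4.94 log2 CPM), since EOAD 2 (−0.65) lies within the LOAD range (−2.63 to 0.91). Of 13 heat-shock genes, 13 lay above 0 and 7 rose over the list alone (median 1.885, camera adjusted p = 1.3e-14), with DNAJB1 at 1.93 ± 1.09 and HSPA1A, whose reads are uncertain because HSPA1B is a near copy, at 2.02 ± 0.63. Immediate early genes (11 of 14 above 0, 3 over the list alone, camera adjusted p = 2.07e-08, ATF3 2.15 ± 0.92), hypoxia genes (16 of 16, adjusted p = 3.21e-08, VEGFA 2.10 ± 0.76) and cholesterol genes (11 of 14, 5 over the list alone, adjusted p = 3.82e-06) were called upward. Interferon-response genes were called downward (18 of 18 below 0, median −1.19, camera adjusted p = 1.49e-05, MX1 −1.44 ± 0.74), although ISG15 stood at 0.45 against hashed LOAD donors alone. With an estimated correlation the 5 lists had adjusted p = 0.0557 to 0.517. Cluster 21, led by stress genes, had a mean share of 37.07% per EOAD donor (23.96 and 50.19).

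In all, 5 of 14252 genes passed, all upward (edgeR), against 5 by DESeq2 (4 up, 1 down). Without the clusters led by stress genes 1 gene passed and LRRC57 stood at −0.10. Leaving out 1 donor gave 3 genes (EOAD 2), 8 (EOAD 1) and 75 (LOAD 33).

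Proliferation genes were called higher in MS than in LOAD microglia, as a list. Of 15 members, 14 lay above 0 (median 2.516, camera adjusted p = 1.98e-11, but adjusted p = 0.368 with an estimated correlation). MKI67, a marker of dividing cells (chromosome 10, 128096659 to 128126385, minus strand), stood at 3.65 ± 1.53, with 50.1 ± 42.8 against 7.64 ± 16.7 CPM (n = 2 and 16), and TOP2A, which encodes topoisomerase II alpha, at 2.96 ± 1.51. Interferon-response genes were called upward (16 of 18 above 0, camera adjusted p = 0.00281, with the antiviral gene MX1 at 1.35 ± 0.61), and the myelin gene MOBP stood at 3.83 ± 0.83 in the oligodendrocyte list (4 of 6 above 0, 1 rose over the list alone, adjusted p = 0.0306). The MS libraries included TH, AWS and, in MS 2, lesion tissue, and no LOAD library was labelled TH or lesion. Tissue and disease therefore cannot be told apart in MS against LOAD. Heat-shock genes (13 of 13 below 0, median −1.571, camera adjusted p = 6.58e-06) and immediate early genes (13 of 14, adjusted p = 0.00281) were called downward. The heat-shock call rests on the single-region donor (DNAJB1 −4.97, HSPH1 −3.24) and not on the hashed donor (DNAJB1 −0.81, HSPH1 0.38). With an estimated correlation the 5 lists had adjusted p = 0.368 to 0.877. Cluster 18 had a mean share of 28.11% per MS donor (0.06 and 56.17). No gene passed by edgeR, where 735 lay under an unadjusted p of 0.05, and none by DESeq2, where 994 did. The interferon list had a median of 1.791 in single-region libraries and was reversed in hashed libraries (camera adjusted p = 0.0902), so its call rests on 1 of 2 donors. With 3 library batches fitted, 211 genes passed, and 21 after LOAD 26 was also left out.

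Oxidative-phosphorylation genes were called higher in PSP than in LOAD microglia and immediate early genes lower, again only as lists. All 30 respiratory genes lay above 0 (median 0.665, camera adjusted p = 4.3e-11, adjusted p = 0.95 with an estimated correlation), with the ATP synthase gene ATP5E at 0.68 ± 0.53 and UQCRB, a complex III gene, at 0.80 ± 0.56 (n = 2 and 16). Of 14 immediate early genes, 13 lay below 0 (camera adjusted p = 0.00206, adjusted p = 0.95 with an estimated correlation), with the transcription factor gene JUN at −1.55 ± 0.81. The members differ between the PSP donors: FOS stood at 9.65 log2 CPM in PSP 2 and 6.39 in PSP 3, ATF3 at 5.05 and −2.63 and JUN at 7.16 and 6.32, so the low FOS and ATF3 rest on PSP 3. Cluster 1 had a mean share of 29.93% per PSP donor (8.68 and 51.18). Both PSP donors belong to barcode set A, and within set A the median of the respiratory list was 0.045 (camera adjusted p = 0.671), so its call rests on LOAD donors of set B. No gene passed by edgeR, where 850 lay under an unadjusted p of 0.05, and DESeq2 called 5, all downward.

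Between regions, microglia of SC expressed less of most homeostatic genes and more of all MHC class II genes than microglia of BA4 of the same 3 ALS donors. P2RY12, the ADP receptor that marks homeostatic microglia (chromosome 3, 151337380 to 151384812, minus strand), fell by 2.92 ± 0.23, the fractalkine receptor gene CX3CR1 by 1.90 ± 0.18 and TMEM119 by 1.39 ± 0.14. Of 14 homeostatic genes, 10 fell and 2 rose over all genes, among the latter CST3, and 12 fell over the list alone (camera adjusted p = 4.3e-09, adjusted p = 0.0849 with an estimated correlation). All 11 MHC class II genes rose (median 1.558, camera adjusted p = 1.7e-18, adjusted p = 0.0378 with an estimated correlation). HLA-DPB1 (chromosome 6, 33075926 to 33087201, plus strand) rose 2.30 ± 0.20, HLA-DRA 1.85 ± 0.19 and CD74, which encodes the class II invariant chain, 0.95 ± 0.18. HLA alleles shift read counts, but both regions of a donor share them. Of 20 lipid-associated genes 13 rose over all genes (median 1.18, camera adjusted p = 1.58e-09, but adjusted p = 0.174 with an estimated correlation), with GPNMB, a lysosomal glycoprotein gene (chromosome 7, 23235967 to 23275108, plus strand), at 3.56 ± 0.66, APOE at 1.59 ± 0.18 and SPP1 at 0.98 ± 0.48, which did not pass. B2M, the MHC class I light chain, rose 1.13 ± 0.22 (5 of 12 MHC class I genes rose, camera adjusted p = 0.00268, but adjusted p = 0.201 with an estimated correlation).

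Among single genes, CXCR4, the CXCL12 receptor (chromosome 2, 136114349 to 136118165, minus strand), rose 6.82 ± 0.90, from 9.42 ± 3.62 to 1099 ± 592 CPM (n = 3, edgeR adjusted p = 0.00134), and the intermediate filament gene VIM (chromosome 10, 17228259 to 17237593, plus strand) rose 6.88 ± 1.25 (adjusted p = 0.00601). SPON1, NRARP and the stress-induced genes ATF3 and NR4A2 rose 6.80 ± 0.86, 6.71 ± 0.75, 6.33 ± 1.05 and 6.30 ± 1.06. THBS1 had 10.5 ± 6.72 CPM in SC and 0.0621 ± 0.108 in BA4. CA8, which encodes a carbonic anhydrase-related protein (chromosome 8, 60187347 to 60281412, minus strand), fell by 4.96 ± 0.36, from 29 ± 28 to 0.912 ± 1.38 CPM (edgeR adjusted p = 4e-07), the transporter gene ABCG2 by 3.94 and the adhesion gene CNTNAP2 by 4.05. NRARP, CXCR4, ATF3 and NR4A2 are also among the leading genes of clusters 22 or 25, stress-led clusters with mean shares of 14.48% and 11.78% of the class per SC library. Cluster 4, with the macrophage marker STAB1 among its leading genes, had 12.96%. In BA4, cluster 13 had 32.9% and cluster 4 14.89%. Oxidative phosphorylation (30 of 30 rose, median 0.962, camera adjusted p = 2.44e-21), hypoxia (14 of 16, p = 2.13e-09, VEGFA 4.49 ± 1.01), immediate early (11 of 14, p = 6.04e-08, FOS 2.56 ± 0.60) and heat-shock genes (10 of 13, p = 5.87e-06, DNAJB1 4.08 ± 0.94) were called upward. These 4 lists lost the call, with adjusted p = 0.174 to 0.421 with an estimated correlation.

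Monocyte markers were called upward in SC (4 of 6 rose over all genes and 6 over the list alone, camera adjusted p = 0.000293, but adjusted p = 0.201 with an estimated correlation), with VCAN at 5.76 ± 1.15 and S100A9 at 2.67 ± 0.78. Cluster 7, led by S100A9 and S100A8 and kept out of the class, held more cells in BA4 than in SC. It held 723 and 152 cells in ALS 5, 71 and 28 in ALS 1, and 1 and 0 in ALS 4. The list was not tested with cluster 7 counted, so part of this call may come from leaving it out. Interferon (4 of 18 rose, camera adjusted p = 0.00497), cholesterol (5 of 14, p = 0.0143) and proliferation genes (3 of 15, p = 0.0166) were called upward and neuron genes downward (2 of 7 fell, p = 0.0337). Proliferation values were largest in ALS 4 (MKI67 4.67, TOP2A 5.21, TYMS 3.85, against 0.85, −0.29 and −0.24 in ALS 1 and 0.89, 2.36 and 0 in ALS 5). Apart from homeostatic and MHC class II genes, the 11 lists called in SC had adjusted p = 0.174 to 0.482 with an estimated correlation. Iron (7 up, 2 down, camera adjusted p = 0.0539), phagocytic (5 up, 3 down, p = 0.42) and border-macrophage genes (4 up, 2 down, p = 0.68) changed in both directions and were not called. In all, 3425 of 12789 genes passed (1961 up, 1464 down, edgeR with donor as block), 2661 by DESeq2, and 99 without the block. Leaving out 1 donor gave 2438 to 2723 genes, and without stress-led clusters 1864 passed.

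**Figure D3:**
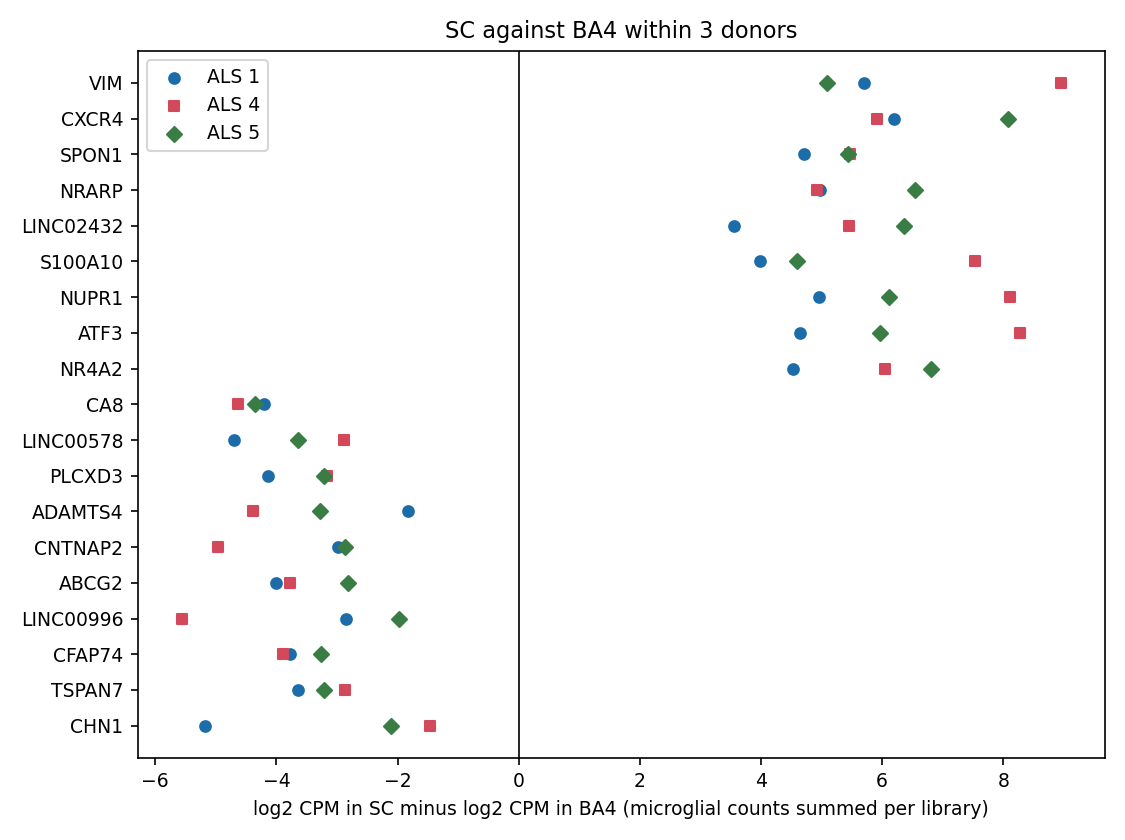
Difference in log2 CPM between SC and BA4 in the microglial class for named genes in each of 3 ALS donors.

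FN microglia differed from BA4 microglia in NRARP, in nuclear receptor genes induced by stress and in MRC1. NRARP rose 6.86 ± 0.83 (edgeR adjusted p = 0.00437), the nuclear receptor genes NR4A2 and NR4A1 rose 5.90 ± 1.17 and 5.50 ± 0.75, and CXCR4 rose 5.63 ± 0.92 (2 donors). These 4 genes are also among the leading genes of the stress-led clusters 22 or 25. MRC1, the mannose receptor (chromosome 10, 17809344 to 17911170, plus strand), fell by 4.76 ± 0.48 (edgeR adjusted p = 0.00145), CA8 by 3.93 and ABCG2 by 3.54 ± 0.44. VPREB1, a surrogate light chain gene, had 40.2 ± 56.8 CPM in FN and 0.0621 ± 0.108 in BA4, with no difference in ALS 4. P2RY12 fell by 1.47 ± 0.25 and TMEM119 by 0.67 ± 0.16, and 4 of 14 homeostatic genes fell over all genes and 6 over the list alone (camera adjusted p = 1.03e-06, but adjusted p = 0.105 with an estimated correlation). HLA-DPB1 rose 1.16 ± 0.22 (3 of 11 MHC class II genes over all genes, 6 over the list alone, camera adjusted p = 1.53e-06, but adjusted p = 0.113 with an estimated correlation). The myelin genes MOBP (chromosome 3, 39467198 to 39529479, plus strand) and MBP rose 5.45 ± 0.92 and 0.77 (2 of 5 oligodendrocyte genes, camera adjusted p = 8.18e-05, but adjusted p = 0.0881 with an estimated correlation). Cluster 1 had a mean share of 26.87% of the class per FN library.

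Immediate early (4 of 14 rose over all genes, 12 over the list alone, camera adjusted p = 5.62e-13), oxidative-phosphorylation (12 of 30 and 27, p = 1.36e-16), lipid-associated (3 of 20 and 12, p = 1.38e-07), hypoxia (1 of 16 and 10, p = 2.59e-07), cholesterol (1 of 14 and 8, p = 0.000111), proliferation (1 of 15, p = 9.54e-06), heat-shock (0 of 13, p = 0.00183) and monocyte lists (0 of 6, p = 0.00329) were called upward in FN. The heat-shock values were larger in ALS 4 (HSPA1A 2.29, HSPH1 1.88, DNAJB1 3.73) than in ALS 1 (−0.31, 0.34 and 1.12). Complement (2 of 11 fell, 9 over the list alone, camera adjusted p = 3.53e-05) and phagocytic genes (3 of 11, p = 0.00183, FCGR1A −0.91 ± 0.20, whose family copies make its reads uncertain) were called downward. So was the border-macrophage list (1 of 8 fell, camera adjusted p = 0.00878), although its median was 0.104 and CD163, another member, stood above 0 in both donors (2.04 and 1.21). All 14 lists lost the call, with adjusted p = 0.0881 to 0.522 with an estimated correlation. In all, 539 of 12789 genes passed (411 up, 128 down, edgeR), 578 by DESeq2, 1 without the block, 225 without stress-led clusters, 234 without ALS 4 and 260 without ALS 1.

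Lipid-associated and MHC class II genes were called higher in microglia of H than of BA9 in 3 donors, without any gene passing alone over all genes. All 20 lipid-associated genes lay above 0 and 9 rose over the list alone (median 0.581, camera adjusted p = 1.24e-11), with GPNMB at 2.05 ± 0.60 and APOE at 0.52 ± 0.17. MHC class II (10 of 11 above 0, 6 over the list alone, camera adjusted p = 7.41e-06), lysosome (14 of 15, p = 0.000106), interferon (17 of 18, p = 0.00621), oxidative-phosphorylation (30 of 30, p = 1.24e-11), hypoxia (15 of 16, p = 0.00543), immediate early (14 of 14, p = 1.65e-09) and heat-shock genes (13 of 13, p = 9.63e-12) were called upward. Homeostatic genes were called downward (10 of 14 below 0, 4 fell and 1 rose over the list alone, camera adjusted p = 0.00621, CX3CR1 −0.84 ± 0.18), as were border-macrophage genes (7 of 8, adjusted p = 0.00621, MRC1 −1.89 ± 0.38). With an estimated correlation these 10 lists had adjusted p = 0.268 to 0.591. Heat-shock values were largest in FTD 1 (DNAJB1 5.62, against 1.68 in LOAD 12 and 0.48 in LOAD 15). Cluster 1 had a mean share of 34.31% of the class per H library, and cluster 10 19.49% over all 12 single-region BA9 libraries. No gene passed by edgeR, where 1558 lay under an unadjusted p of 0.05, while DESeq2 called 204 of the 888 genes that its own filter left to be tested, and edgeR called 75 without the low-count filter and 295 with conflicting labels read by tissue tag.

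In SN, 2 genes of border macrophages and 1 of vessels stood below BA9 of the same 2 donors, and none passed alone. MRC1 stood at −2.92 ± 0.46 and LYVE1, a hyaluronan receptor gene of perivascular macrophages, at −3.20 ± 1.04 (5 of 8 border-macrophage genes below 0, camera adjusted p = 0.00106). FLT1, a VEGF receptor gene, stood at −1.63 ± 0.49 (3 of 5 endothelial and mural genes below 0, camera adjusted p = 0.0129). Lipid-associated (17 of 20 above 0, camera adjusted p = 0.000232), interferon (16 of 18, p = 0.000618), MHC class II (9 of 11, p = 0.00762) and oxidative-phosphorylation genes (28 of 30, p = 0.000232) were called upward, and the 6 lists had adjusted p = 0.527 to 0.677 with an estimated correlation. DLBD-PD 3 carries the lipid-associated and interferon calls (GPNMB 1.84, IFI44L 2.09, ISG15 1.13), while LOAD 15 stood near 0 (0.11, −0.13 and −0.21), and the MHC class II gene HLA-DPB1 stood at 0.75 and 0.15. Cluster 1 had a mean share of 30.1% of the class over 3 single-region SN libraries, 1 of them too small to be tested. No gene passed by edgeR (500 under an unadjusted p of 0.05) and 5 passed by DESeq2.

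In BA4 against BA9, in 2 ALS donors, oxidative-phosphorylation (30 of 30 below 0, camera adjusted p = 1.7e-22), interferon (16 of 18, p = 7.05e-08) and proliferation genes (14 of 15, p = 0.0232) were called downward and lipid-associated genes upward (13 of 20 above 0, p = 0.0311). The 4 lists had adjusted p = 0.704 to 0.732 with an estimated correlation. ALS 4 carries the values of the named respiratory genes (ATP5E −0.5, COX4I1 −0.52, against −0.04 and 0.13 in ALS 1), while the named interferon genes lay lower in ALS 1 (IFI44L −1.23, MX1 −0.72, IFIT3 −0.83, ISG15 −0.9) than in ALS 4 (−0.01, 0.04, −0.61 and −0.36). No gene passed in BA4 against BA9 by edgeR (235 under an unadjusted p of 0.05) or by DESeq2 (119).

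Of 74 list calls made with the preset correlation, 4 hold with an estimated one: cholesterol genes in ALS, monocyte and iron genes in DLBD-PD, and MHC class II genes in SC. Chemokine and NF-kB genes were called in no comparison (lowest camera adjusted p = 0.0578, in SN), and neither were T cell markers (lowest adjusted p = 0.112, in ALS).

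**Figure D4:**
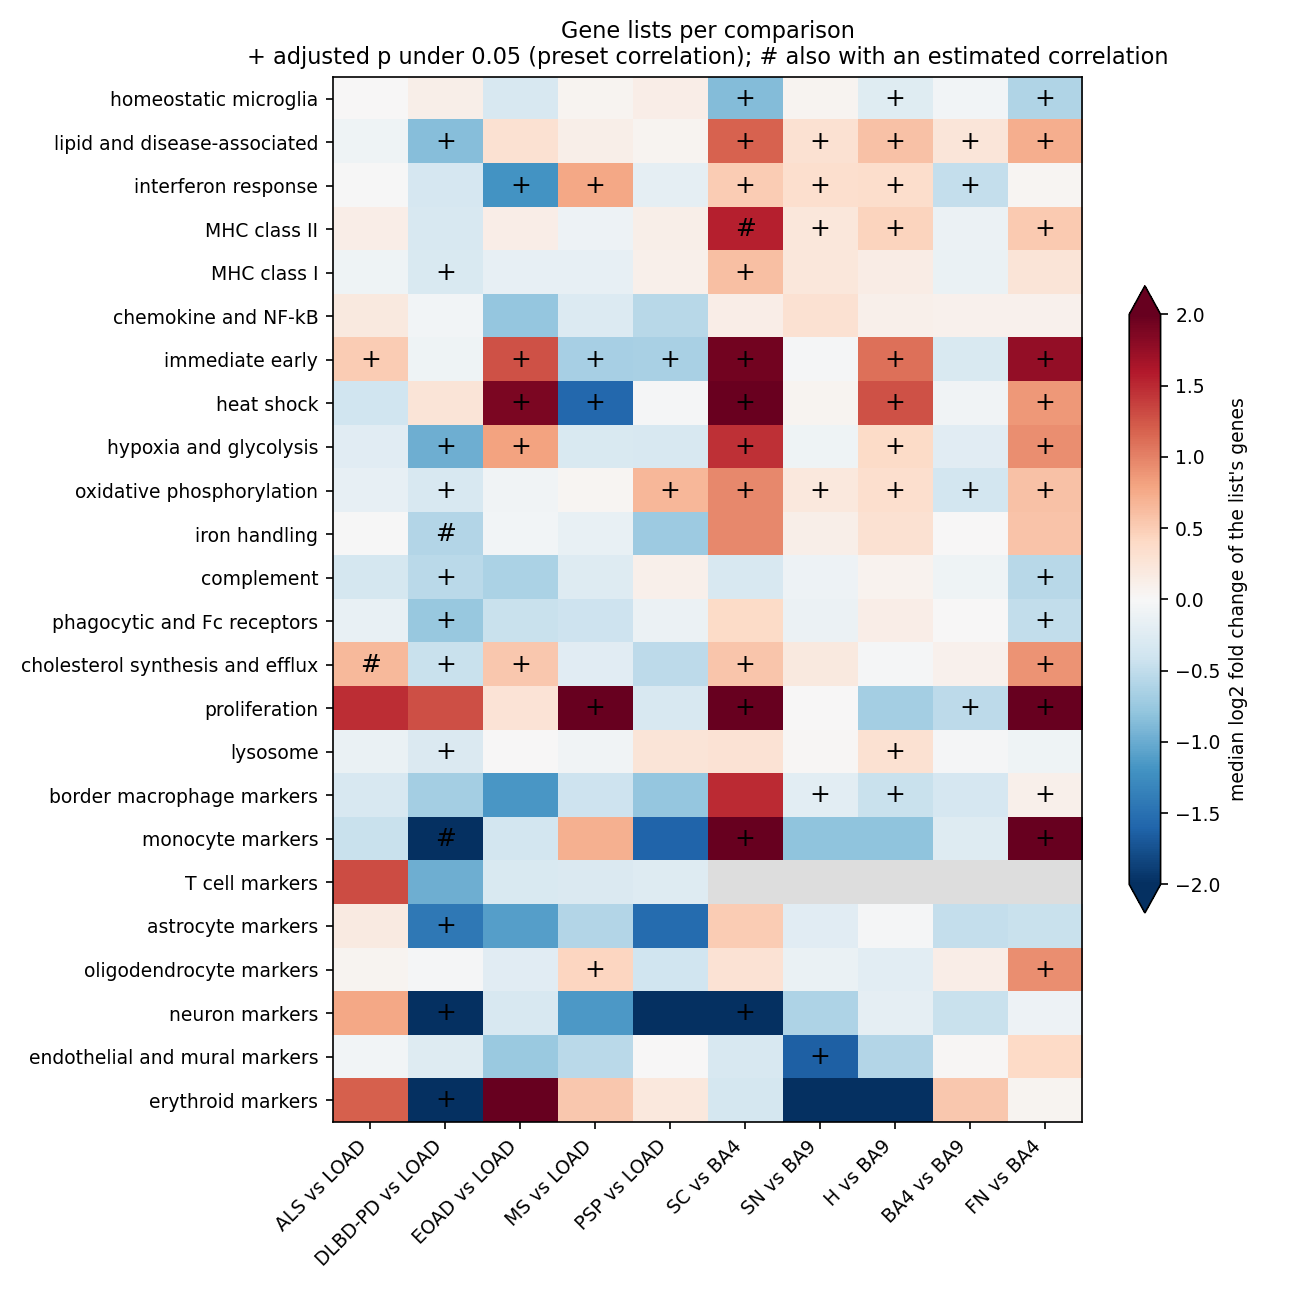
Median log2 fold change of each gene list in each comparison, clipped at ±2; a plus sign marks lists called by camera with the preset correlation, a hash sign those also called with an estimated one, and grey lists were not tested. Monocyte and erythroid lists include genes with 0 counts in a group, so the size of their medians is not read.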

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

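No test in this part was chosen after its result was seen. Each share and key gene was screened within its group with the Dixon test, and 5 of 121 sets had a member set apart, where chance alone marks about 1 set in 20. T and NK-like cells were 12.786% of the cells in ALS 7 and 1.603 to 6.325% in the other 7 ALS donors. Astrocyte-like cells were 1.297% in ALS 1 and 0 to 0.498% in the other 7. Erythroid-like cells were 3.632% in ALS 1 and 0 to 0.061% in the other 7. Neuron-like cells were 7.677% in ALS 1 and 0 to 3.326% in the other 7. TMEM119, a homeostatic microglial gene, had a log2 CPM of 6.54 in the BA9 library of LOAD 12 and 7.61 to 7.92 in the other 5 BA9 libraries. Surface antibodies gave 4766502 UMIs in the hashed library of ALS 8 and 5356774 in that of CNTRL 1. The values were 2 to 193 in 19 other sums of hashed libraries, where the 2 pools without a group were summed as 1.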

How the results depend on the processing

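Chosen only after the data were seen were the tests with barcode sets, 3 library batches, clusters left out or added and conflicting labels left out, the lists by library format in MS, EOAD and PSP, the shares outside SC, in BA9 alone, with matching labels alone, with conflicting labels read by title or tissue tag or without 1 donor, and the stricter cells and doublets left out for the T and NK share of SC against BA4. The other alternatives were written beforehand. Of 251 gene counts, 182 stayed within 1.5 times of the reported one and 69 moved further. Of 260 list values, 108 kept the call, 150 lost it and 2 changed sign. Of 7538 values of named genes, 6892 stayed as reported, 317 no longer passed and 135 newly passed. A further 192 changed sign without passing in either fit, and 2 changed sign in genes that had passed. Of 218 share values, 188 stayed as reported. Values that stayed as reported include those that passed in neither test, so these counts do not measure how well calls hold.

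Among called results, signs changed for MSMO1 in ALS in BA9 libraries alone (−0.02), for LRRC57 in EOAD without stress-led clusters (−0.10), for the interferon list in MS in hashed donors (camera adjusted p = 0.0902), for the MHC class I list in DLBD-PD in barcode set A (adjusted p = 0.973) and for the neuron-like share in hashed donors (−0.116 points). The astrocyte-like share, which was not called (0.09 points), stood at −0.345 in hashed donors, −0.002 in set B and −0.048 without ALS 1. The T and NK difference between ALS and LOAD was 3.991 points in hashed donors and 3.121 in set B, neither passing, 2.789 in single-region donors with matching labels, −0.533 outside SC and −0.571 in BA9 alone. With ALS 3 it was 0.701 without SC by title and −0.727 by tissue tag. Counting cluster 7 left a microglial difference of −6.493 points.

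With DESeq2 the counts were 193 in ALS, 93 in DLBD-PD, 5 in PSP, 5 in SN and 204 in H, where only 888 genes were tested. Without the low-count filter they were 2 in DLBD-PD, 1 in MS and 75 in H. Stricter cells gave 22 in EOAD, 11 in H and 301 in FN. Cells with P2RY12, CX3CR1 or CSF1R alone gave 34 in H and 282 in FN, and a minimum of 20 cells gave 7 in H. In single-region donors 379 genes passed in ALS, and in hashed donors 0 in ALS and 53 in DLBD-PD. BA9 libraries alone gave 65 in ALS. With 3 library batches the counts were 1015 in ALS, 32 in EOAD and 211 in MS, and after LOAD 26, the only single-region LOAD donor of set B, was also left out, 438, 27 and 21, with 1 in DLBD-PD. Set A alone gave 2 in DLBD-PD, and set B alone 511 in ALS, 11 in EOAD and 2 in MS. Without macrophage-led clusters the counts were 49 in ALS, 1 in DLBD-PD, 1 in EOAD and 4 in H. Without stress-led clusters they were 43 in ALS, 1 in EOAD, 1864 in SC, 1 in SN and 225 in FN. Leaving out libraries with conflicting labels gave 1 in DLBD-PD, and reading them by tissue tag 13 in SN and 295 in H. Of the list calls, 4 hold with an estimated correlation and 27 with fry.

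No paired analysis was possible because donor numbers of different diseases name different persons. In the region comparisons donors are paired, and without the replicate block the counts were 99 in SC, 1 in H and 1 in FN, while SN and BA4 against BA9 stayed at 0.

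Leaving out 1 donor gave 6 to 73 genes in ALS against LOAD: 13 without ALS 3, 7 without ALS 4, 17 without ALS 5, 73 without ALS 6, 13 without ALS 7, 13 without ALS 8, 12 without ALS 9, 17 without LOAD 11, 10 without LOAD 12, 6 without LOAD 13, 7 without LOAD 14, 9 without LOAD 15, 40 without LOAD 2, 17 without LOAD 20, 42 without LOAD 33 and 73 without LOAD 34. In EOAD it gave 8 without EOAD 1, 3 without EOAD 2 and 75 without LOAD 33. In DLBD-PD it gave at most 1 (LOAD 26), in MS at most 10 (MS 2) and in PSP 0. In SC it gave 2438 to 2723, in FN 234 without ALS 4 and 260 without ALS 1, in H at most 6 and in SN at most 1 (both LOAD 15), and in BA4 against BA9 0. Fits that leave 1 donor in a group assume that it varies as the other groups do. The disease comparisons with 2 donors recovered few simulated changes of log2 1, so the counts of 0 in MS and PSP do not exclude changes of that size.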

Other observations

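The genes of the SC paragraph, the antibody values and the tissue-mix test of the T and NK share were chosen only after the values were seen, while the other tests and what would count against them were written before. In SC microglia, members of the iron, border-macrophage and phagocytic lists changed in opposite directions. FTH1, the ferritin heavy chain gene, rose 2.49 ± 0.28 from 1544 to 9082 CPM (n = 3 donors, edgeR adjusted p = 2.65e-05), the hemoglobin scavenger receptor gene CD163 rose 3.60 ± 0.84 from 62.8 to 341 CPM (adjusted p = 0.0174), and the iron exporter gene SLC40A1 fell by 1.07 ± 0.17 (adjusted p = 0.000249). F13A1 rose 4.12 ± 0.96 (edgeR adjusted p = 0.0169) and SIGLEC1 2.36 ± 0.82 (adjusted p = 0.043), whereas MRC1 fell by 2.95 ± 0.35 (adjusted p = 0.000303), so the border-macrophage markers split. MARCO, a scavenger receptor gene, rose 5.62 ± 1.06 (edgeR adjusted p = 0.00607) and FCGR2B, the inhibitory Fc receptor gene whose copies share reads, 4.22 (adjusted p = 0.00209), whereas MERTK, the receptor for apoptotic cells, fell by 1.39 ± 0.14 (adjusted p = 6.85e-06).

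Surface antibodies were counted in the hashed libraries of ALS 8 and CNTRL 1, 1 donor each and therefore untested. Microglia had medians of 240 and 120 UMIs of HLA-DR, 87 and 49 of CD64 and 95 and 55 of CD11c (4456 and 5707 cells). T and NK-like cells had 298 and 88.5 of CD45, 188 and 39 of CD29, 65 and 24.5 of CD69 and 27 and 20 of HLA-DR (179 and 96 cells). T and NK-like cells were 2.026% in ALS/FTD 1 (95% interval 1.721 to 2.368), 1.349% in CNTRL 1 (1.094 to 1.644) and 1.211% in FTD 1 (0.859 to 1.659), intervals that cover counting error only.

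SC tissue entered the ALS and not the LOAD libraries, which may account for the higher T and NK share in ALS. In single-region donors with matching labels (3 ALS, 6 LOAD) the difference was 2.789 points with their SC libraries and −0.533 without them, and this tissue mix fits. Without SC and with ALS 3, whose labels conflict, it was 0.701 points by title and −0.727 by tissue tag, and hashed donors cannot be split by region. For the genes, fold changes of hashed ALS against LOAD correlated with those of SC against BA4 in other donors (r = 0.361 and Spearman 0.380 over 8693 genes, which are not independent replicates; one-sided permutation p = 0.0729 over 1001 relabellings, 95th percentile 0.387). An r within that percentile had been set beforehand as counting against a tissue mix, but that rule was wrong, because a value so close under it excludes nothing, so tissue mix and disease cannot be told apart for these genes. Of 30 splits of the donors within library format, 1 gave as many genes as the real 26, namely the real one itself (highest other 3), which argues against an arbitrary grouping. The splits were made within format and not within barcode set, which nearly coincides with disease in single-region donors, so a difference between the sets stays open. A difference between the diseases themselves stays open.

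For the 3425 genes that differ between SC and BA4 microglia, RNA of T and NK cells could explain little: it made up 0.1997% of the SC sums and predicts 0.0321% of the observed median log2 fold of 0.94 over 1961 higher genes. Cells in a stress response could explain part of it, since stress-led clusters held 37.4% of the SC and 0.0592% of the BA4 cells of the class. Without them 67.4% of the median absolute log2 fold was left (0.849 against 0.573), and 1654 of 3362 genes still passed, a value between the bounds set beforehand, so stress response and region cannot be told apart. Of 4 splits within donors, 1 gave as many genes, the real one (highest other 0), and 4 splits are too few to exclude chance. A difference between the regions themselves stays open.

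In 13 libraries, 1393 cells expressed SST, MARCKSL1, MDK, TUBB2B, STMN2 and CRABP1, genes high in neural precursors and interneurons, at 778.61 to 2102.51 CPM against 0.06 to 11.48 in the other cells. They reached 15.49% of the cells in LOAD 15 BA9, 11.52% in LOAD 14 and 11.46% in PSP 2, and 1388 of them lay in barcode set A. Their barcodes recurred between libraries 16.4 times as often as those of other cells (2111 of 746892 possible pairs against 21798 of 126602713). This fits carry-over from 1 outside library, which may be the source of these cells. Barcodes of other cells were shared between libraries too, and the test takes them as its baseline. It therefore cannot tell whether carry-over also reached other cells, microglia included. Doublets with microglia are unlikely, because the C1Q share of the 1393 cells was 2.66% of that in microglial cells (0.0331% against 1.24% of UMIs). Which library they came from stays open.

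In DLBD-PD against LOAD, 30 of 30 splits within format gave at least the real 0 genes, as any split must, so that count decides nothing. The split of DLBD-PD 3, DLBD-PD 4, LOAD 15 and LOAD 26 from the others gave 279 (highest other), which points to a structure of the samples, and it puts both single-region donors of barcode set B on the same side. In H against BA9, 4 of 4 splits gave at least the real 0 (highest other 0), which decides nothing for the same reason, and there are too few.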
